A study of Mus musculus with 11 samples.

How the data were processed

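Total RNA of 11 mouse stem cell samples was measured on MouseRef-8 v2 bead arrays, with 2 arrays in each of the groups ESC, EpiSC, Epi-Sox2, EpiSC-GFP+ and EpiSC-GFP- and 1 array of T9-EpiSC. Groups and replicate numbers were taken from the sample titles. Per the labels, RNA was amplified linearly with 12 h of in vitro transcription, and the arrays within a group are biological replicates. The deposited scanner table holds, for each of 25697 probes, the mean bead intensity on each array, not normalized per the study's design text and with no negative values that a background subtraction would leave, and a detection p-value, which per the file headers the authors' scanner software (BeadStudio 3.2 per the submitters' processing notes) attached to each probe. The deposited series matrix holds log2 values of the same probes made by the authors, and the processing notes name lumi and RMA with no order. Each of its 11 columns had a median of 2.64 and a rank correlation of 1 with the intensities of its array. The values are on a log2-like scale after quantile normalization, and how background was removed and whether the scale was otherwise shifted stay unknown. The matrix served only as an alternative.

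Intensities were corrected with the normexp model of neqc, using the detection p-values and an offset of 16, quantile-normalized and taken to log2 with limma 3.58.1 in R 4.3.3. Probes with a detection p-value under 0.01 on at least 2 arrays were kept (13048 probes). Gene names came from the platform annotation, updated through Entrez gene numbers, of which 23962 were found in the gene table. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 had none. Each gene was represented by the probe with the highest mean over all arrays, and a probe without a symbol stood for itself, which gave 8873 genes and 747 unnamed probes, 9620 in all, called genes in the text. For 2426 genes more than 1 probe passed the filter. Differences were tested with limma's linear model and empirical Bayes moderation over all 11 arrays, with 1 mean per group, 5 residual and 4.64 prior degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Where no probe of a gene was detected on either array of a group, the fold is a bound against the higher of the gene's own signal and the lowest detected signal on each array of that group.

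Lists of genes of pluripotent, embryonic, germ line and feeder cell types, of signalling pathways and of other cell states were fixed before the data were examined, as were the comparisons, the tests and the alternatives not marked otherwise. The 20 lists with at least 5 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. For lists that passed at the preset value the estimate was negative, from -0.016 to -0.101, except in the fibroblast list (0.015). Apart from that list, the higher adjusted p-values with an estimated correlation therefore do not reflect a higher correlation. Named genes are Pou5f1, Sox2 and Nanog, the 8 largest rises and 8 largest falls of each main comparison among called genes whose groups did not overlap and whose symbol is not a clone or predicted-gene name (3 of each for the sorted fractions against ESC), and up to 4 members of each list with the largest difference. Further genes are named as examples where stated. Overlaps of calls were tested with Fisher's exact test. T9-EpiSC, with 1 array, was described by its differences and by percentiles among 10000 random lists.

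The linear model and its threshold were tested on simulated arrays with the spread of the real ones and independent noise. Values were drawn after background correction, normalization, filtering and choice of probes, so those steps were not tested. In each run 200 of the 9620 genes were changed, fewer than were called in any comparison of the data. The 3 runs shared means, spread and numbers of arrays, so differences between them are random. Of 50 genes changed by a log2 difference of 1, 72% were recovered in EpiSC against ESC, 74% in Epi-Sox2 against EpiSC and 64% in EpiSC-GFP+ against EpiSC-GFP-, each among 9620 genes. At a log2 difference of 2 these shares were 98%, 100% and 100%, and at 0.5 they were 20%, 8% and 12%. False calls made up 2.03%, 5.37% and 5.48% of the calls, and 0 genes were called with no change.

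The alternatives were normexp with an offset of 50, no background correction, cyclic loess, median scaling, the authors' values, no detection filter, a filter on both arrays of a group, all probes, only the arrays of the groups compared, an intensity trend in the variance, a threshold of 1 log2 unit, the replicate number as a block and leaving out each array. Genes whose probes all passed in one direction, and a run without the T9-EpiSC array, were added after the data were seen. The slide as a block was not run, because the tables name no slide. Replicate numbers did not pair the arrays, as the correlations of their deviations ran from -0.018 to 0.086.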

Results

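Transcript levels were measured with mouse expression bead arrays in 6 kinds of pluripotent stem cell culture, on 11 arrays in all. ESC are male mouse embryonic stem cells, the counterpart of the early embryo before implantation. EpiSC are epiblast stem cells of the GOF18 line, a cell type that resembles the epiblast after implantation, and Epi-Sox2 are GOF18 cells that overexpress the transcription factor Sox2 in conditioned medium (CM). EpiSC-GFP+ and EpiSC-GFP- are fractions of the E3 line that were grown in the same kind of medium and sorted by flow cytometry for a green fluorescent reporter of Oct4, the protein encoded by Pou5f1. Each of these 5 groups had 2 arrays, labelled as biological replicates. A single array held T9-EpiSC, from a line grown on CF1 embryonic fibroblasts and harvested without them 2 days after Fgf2 was withdrawn.

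The mean signal per array ran from 199.7 in EpiSC-GFP- replicate 2 to 623 in ESC replicate 1, and 9250 to 11675 of the 25697 probes were detected. ESC replicate 2 read 595, and no array outside ESC exceeded 371. The number of arrays limits the precision of every value. Replicates correlated at r of 0.988 to 0.996 across the 9620 genes and unnamed probes tested, which are not independent replicates. The mean correlation of ESC with the other groups was 0.788 to 0.856. It was 0.973 between EpiSC and Epi-Sox2 and 0.965 between EpiSC-GFP+ and EpiSC-GFP-. Average linkage clustering split ESC from all other arrays first, then T9-EpiSC, then the fractions of E3 from the GOF18 cells. Unless stated otherwise, values are log2 differences ± standard error (SE) with n = 2 arrays per group, and adjusted p-values are from limma. Every gene called had both arrays of one group above both arrays of the other.

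The first comparison asked how epiblast stem cells of the GOF18 line differed from embryonic stem cells. As the EpiSC arrays came from a single line, the p-values measure the spread between arrays and not between lines. A difference of cell type cannot be told apart from one of line here, nor where the E3 fractions are set against ESC. Fgf5 and Fgf8, growth factors of the epiblast and the primitive streak, were not detected on the ESC arrays and were at least 26.0-fold and at least 17.1-fold higher in EpiSC (adjusted p = 2.2e-08 and 2.25e-07). Otx2, a homeobox gene of the epiblast and the anterior brain, rose by 5.33 ± 0.14 (adjusted p = 5.53e-09), from a signal detected on 1 of 2 ESC arrays. Ooep, an oocyte gene, fell by 6.86 ± 0.12, and Dppa5a, a gene of naive pluripotent cells, fell by 6.38 ± 0.12 (adjusted p = 9.16e-10 for each). Dnmt3l, a cofactor of the enzymes that methylate DNA anew, fell by 6.46 ± 0.13 (adjusted p = 9.16e-10). A bound such as "at least 26.0-fold" is given where a gene was not detected on either array of a group, and sets the brighter group against the lowest detected signal of the arrays of the dimmer group.

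The core pluripotency factors did not move together between EpiSC and ESC. Nanog fell by 3.02 ± 0.19 (adjusted p = 5.79e-07) and Sox2 fell by 1.42 ± 0.13 (adjusted p = 6.66e-06), while Pou5f1 was higher by 1.07 ± 0.13 (adjusted p = 4.52e-05). The size of the Sox2 fall depended on the probe, as the other Sox2 probe read 9.85 on each ESC array and was not detected on either EpiSC array. The other detected Pou5f1 probe differed by -0.04 and did not pass the test. The remaining largest rises were those of Gbp2, an interferon-induced guanylate-binding protein, at least 31.8-fold, the sulfotransferase gene Chst1, at least 34.4-fold, the carbonic anhydrase gene Car14 (4.89), the glutaredoxin gene Glrx (4.82) and the complement inhibitor Cd59a (4.78). The remaining largest falls were those of the homeobox gene Rhox5 (-6.20), Klhl13 (at least 48.2-fold lower), Rbmxl2 (at least 47.3-fold lower), the microtubule regulator Stmn1 (-5.43) and Cacybp (-5.41). The Klhl13 and Cacybp probes were among 93 that read above 8 on both ESC arrays and under 6 on the other 9. A probe of Hprt did so too, at 4.75 and 5.04 in EpiSC, while another Hprt probe read 12.26 and 11.66 on those arrays. The Klhl13 and Cacybp falls may therefore be specific to the probe. Stmn1 had only 1 probe past the filter, so this stays open for its fall too.

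Among the gene lists, all 18 tested members of the naive pluripotency list fell in EpiSC, with the same count adjusted over the list alone (camera adjusted p = 2.25e-13, and adjusted p = 0.00798 with an estimated correlation). They included Ooep, Dppa5a, the nuclear receptor gene Esrrb (-4.95) and the adhesion gene Jam2 (at least 27.2-fold lower). Of 14 tested members of the epiblast and primed pluripotency list 11 rose and 2 fell, among them Otx2, the neural and epiblast factor Pou3f1 (3.52) and Igfbp3 (3.04), with the same counts adjusted over the list alone (camera adjusted p = 0.00397). This list had an adjusted p = 0.0982 with an estimated correlation. In the germ line list 9 of 11 members fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 4.99e-05, and adjusted p = 0.0492 with an estimated correlation). Tex19.1 (-3.87), Dppa3 (-3.84) and the meiosis gene Stra8 (at least 5.14-fold lower) were among them.

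Of 16 tested fibroblast marker genes 9 fell in EpiSC, 3 rose and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0348). The list had an adjusted p = 0.207 with an estimated correlation, 0.0551 without background correction and 0.0524 without EpiSC replicate 2. Its members included the collagen crosslinking enzyme Lox (at least 6.14-fold lower), the matrix gene Fbln2 (-2.99, detected on 1 of 2 EpiSC arrays) and the smooth muscle actin Acta2 (-2.70). The brightest probe of the matrix gene Ccn1 was higher (1.93), whereas its other 2 probes were called lower, down to -0.95.

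Other lists had members in both directions between EpiSC and ESC and no shift that passed. In the shared pluripotency list 6 members fell and 2 rose of 11 (camera adjusted p = 0.0614), with Dppa4 (-4.93) and the Nodal co-receptor Tdgf1 (-2.98) lower, and the shift passed with an offset of 50 (0.0410), without background correction (0.0409), with cyclic loess (0.0394), with median scaling (0.0369), without the detection filter (0.0409) and without ESC replicate 2 (0.0431). In the Nodal and activin list 7 rose and 5 fell of 13 (camera adjusted p = 0.983), among them the inhibitor Lefty1 (2.24) and the transcription factor Foxh1 (1.97). In the FGF and ERK list 6 rose and 5 fell of 15 (7 and 6 adjusted over the list alone, camera adjusted p = 0.983), with Fgf5 and Fgf8 higher and Fgf4, a growth factor of the naive state, lower (-2.05). In the Wnt list 4 rose and 5 fell of 11 (camera adjusted p = 0.615), with Wnt8a at least 13.7-fold higher and the caudal gene Cdx1 at least 8.56-fold lower. The Wnt8a bound is for its brightest probe, and the least changed of its 3 probes rose by 1.32. In the BMP list 2 rose and 5 fell of 11 (camera adjusted p = 0.139), with Bmp4 (-2.97, detected on 1 of 2 EpiSC arrays) and the inhibitors of differentiation Id2 (-2.75) and Id1 (-2.12) lower. In the primitive streak and mesoderm list 5 rose and 5 fell of 11 (camera adjusted p = 0.969), with the homeobox gene Gsc 2.83 higher (detected on 1 of 2 ESC arrays) and Wnt3a at least 2.40-fold lower.

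Of the remaining lists in EpiSC against ESC, the epithelial list had 6 members higher and 2 lower of 13 (camera adjusted p = 0.832), with the tight junction receptor Lsr 2.46 higher and the keratin gene Krt19 at least 3.55-fold higher, while the cadherin Cdh1 was lower, at means of 8.68 and 10.68. The mesenchymal list had 3 higher and 4 lower of 12 (3 and 2 adjusted over the list alone, camera adjusted p = 0.969), with the matrix genes Mmp2 (2.17) and Sparc (1.41) higher. The imprinted list had 6 higher and 5 lower of 14 (camera adjusted p = 0.983), with Grb10 2.71 higher and Mest lower (-2.53). The endoderm list had 4 higher and 5 lower of 11 (camera adjusted p = 0.560), the neuroectoderm list 3 higher and 1 lower of 5 (camera adjusted p = 0.832), and the trophectoderm list 2 higher and 5 lower of 9 (camera adjusted p = 0.303). Apoe (-2.29), the intermediate filament gene Nes (2.37, and 0.58, not called, for its other probe) and the trophoblast factor Tfap2c (-3.35) were members of these 3 lists in turn. The DNA methylation list had 1 higher and 4 lower of 8 (camera adjusted p = 0.0981, and 0.0489 with median scaling), with Uhrf1 lower (-1.31) and Dnmt3b higher (1.12). The cell cycle list had 5 higher and 4 lower of 16 (camera adjusted p = 0.832), the glycolysis and hypoxia list 3 higher and 5 lower of 13 (camera adjusted p = 0.303), and the immediate early list 5 higher and 3 lower of 13 (camera adjusted p = 0.969). Pcna (-4.27), Pdk1 (-1.77) and Fos (-2.20) were the respective largest differences. Pcna had only 1 probe past the filter, which read 9.83 in ESC and 6.10 in T9-EpiSC, so its fall may also be specific to the probe. In the streak, FGF, Wnt, mesenchymal, cell cycle and immediate early lists the median and the mean difference had opposite signs. The Hox and Cdx list, with 1 higher and 2 lower of 4 tested members, and the sex-chromosome list, with 0 higher and 2 lower of 2, were too short for a list test, and the Y-linked gene Eif2s3y was lower in EpiSC (-1.72).

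In EpiSC against ESC 6408 of 9620 genes passed, 3889 higher and 2519 lower, and 3109 of them differed by at least 1 log2 unit. The share of calls that were higher was 60.7%, and 48.9% with cyclic loess in place of quantile normalization, where the median difference of all genes moved from 0.22 to 0.01. Probes of one gene often disagreed here. Of 2426 genes with more than 1 detected probe, 308 had probes called in opposite directions. The number was 2 in Epi-Sox2 against EpiSC and 24 in EpiSC-GFP+ against EpiSC-GFP-, where fewer genes were called. All probes were called higher for 447 of the 2426 genes and lower for 338. These numbers were 79 and 68 in Epi-Sox2 against EpiSC, and 92 and 75 in EpiSC-GFP+ against EpiSC-GFP-. Named genes were mostly chosen for large differences. Of named genes with more than 1 detected probe, 19 of 25 had all probes called in one direction here, 12 of 27 in Epi-Sox2 against EpiSC and 7 of 25 in EpiSC-GFP+ against EpiSC-GFP-, and sizes given for 1 probe differed from those of others, as for Gbp2 (1.15 for its other probe) and Jam2 (-1.11 for the least changed of 4).

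**Figure D1:**
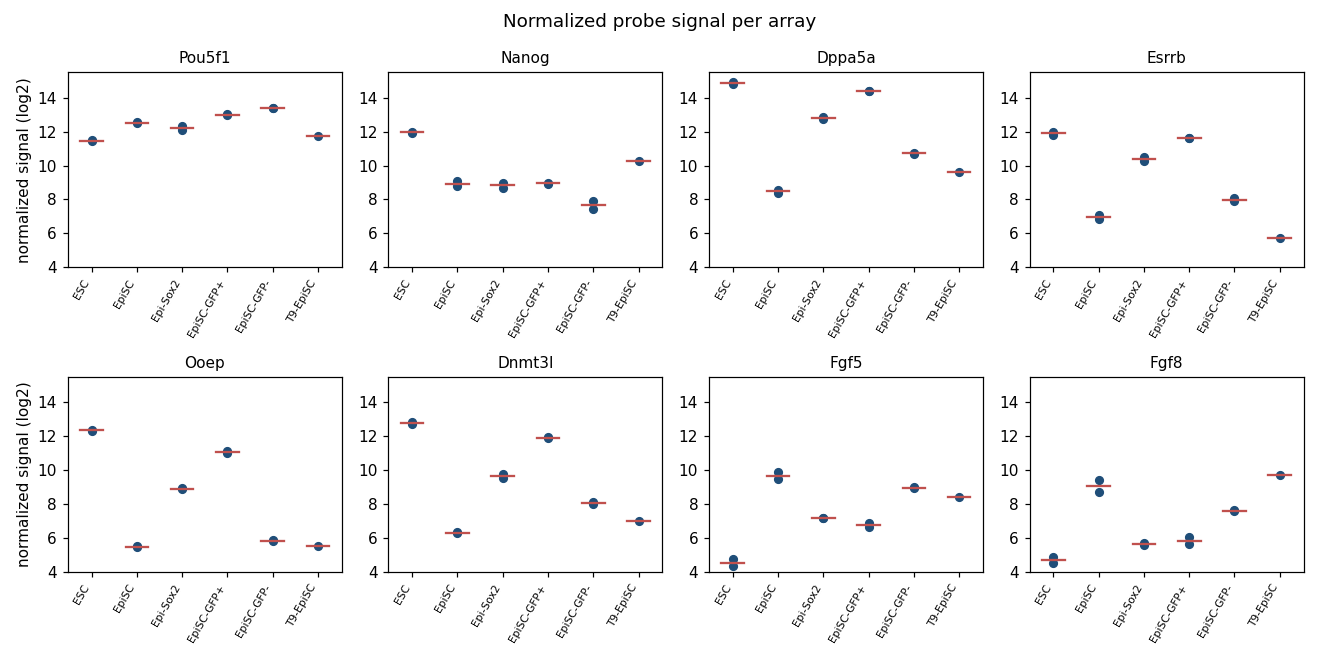
Normalized log2 signal of 8 genes (vertical axis) on each array of the 6 kinds of culture (horizontal axis). Dots are arrays and bars are group means. Dppa5a, Esrrb, Ooep and Dnmt3l were higher in Epi-Sox2 than in EpiSC and higher in EpiSC-GFP+ than in EpiSC-GFP-, whereas Fgf5 and Fgf8 were lower, and Pou5f1 was high on every array.

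The second comparison asked what Sox2 overexpression in GOF18 cells went with. In Epi-Sox2 the Sox2 signal was 0.94 ± 0.13 higher than in EpiSC, 1.91-fold (adjusted p = 0.00131). The same probe read 8.38 and 8.48 on the Epi-Sox2 arrays, and only the EpiSC arrays read lower (7.61 and 7.38). It read higher in ESC (8.97 and 8.86), EpiSC-GFP- (8.85 and 8.90), EpiSC-GFP+ (9.31 and 9.23) and T9-EpiSC (8.58). The other Sox2 probe was also called higher in Epi-Sox2 than in EpiSC (0.57), at a low signal of 5.01 and 5.07. No probe positions were used, so whether either probe reads the overexpressed transcript is not known. Dppa5a rose by 4.33 ± 0.12 (adjusted p = 8.58e-08), Esrrb by 3.43 ± 0.15 (adjusted p = 8.76e-07), Dppa4, a chromatin protein of pluripotent cells, by 3.70 ± 0.11 (adjusted p = 8.58e-08, with 0.24 for the lowest of its 3 probes) and Dnmt3l by 3.33 ± 0.13 (adjusted p = 4.33e-07). Fgf8 fell by 3.44 ± 0.23 (adjusted p = 1.84e-05) and Fgf5 fell by 2.49 ± 0.17 (adjusted p = 2.51e-05). Gsc, a homeobox gene of the gastrula organizer, was at least 7.28-fold lower and no longer detected.

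Pou5f1 differed by -0.30 ± 0.13 (adjusted p = 0.122) and Nanog by -0.10 ± 0.19 (adjusted p = 0.753) between Epi-Sox2 and EpiSC. The Pou5f1 difference passed without background correction (adjusted p = 0.0296) and with an intensity trend in the variance (0.0244). The other largest rises were those of Rbmxl2 (at least 14.99-fold), Vstm2l (3.89), Ooep (3.41) and the glutathione transferase gene Gstp2 (3.25, detected on 1 of 2 EpiSC arrays). The other largest falls were those of the homeobox gene Lhx1 (at least 2.92-fold lower), Ndrg1 (-2.02), Them5 (-1.98, detected on 1 of 2 Epi-Sox2 arrays), the sulfotransferase gene Chst7 (-1.96) and the trypsin inhibitor Spink1 (-1.86).

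In Epi-Sox2 15 of 18 tested naive pluripotency genes rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 6.58e-17, and adjusted p = 0.00453 with an estimated correlation). Besides Dppa5a, Esrrb and Ooep they included the homeobox gene Gbx2 (3.06) and the zinc finger gene Zfp42 (2.71). Of 11 primitive streak and mesoderm genes 6 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 6.87e-04). Fgf8, Gsc, Lhx1 and the Wnt-responsive factor Sp5 (-0.70, a call lost without Epi-Sox2 replicate 1, adjusted p = 0.0774) were among them, and the list had an adjusted p = 0.0734 with an estimated correlation. Of 11 germ line genes 5 rose and 0 fell, with the same counts adjusted over the list alone, led by Tex19.1 (2.28) and Dppa3 (2.07) (camera adjusted p = 0.00209). This list had an adjusted p = 0.0734 with an estimated correlation.

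Of 8 DNA methylation genes 3 rose in Epi-Sox2 and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00209). They were Dnmt3l and the stress-inducible genes Gadd45a (1.04) and Gadd45b (0.88, a call lost without Epi-Sox2 replicate 1, adjusted p = 0.0662), and the list had an adjusted p = 0.0734 with an estimated correlation. In the epithelial list 4 of 13 genes rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0177). The tight junction genes Cldn4 (1.63) and Tjp3 (0.91) and the protease gene St14 (0.74) rose, the last a call lost with the authors' values (adjusted p = 0.0628) and without Epi-Sox2 replicate 1 (0.0728), and the list had an adjusted p = 0.108 with an estimated correlation and 0.0924 without EpiSC replicate 1. In the trophectoderm list 3 of 9 genes rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0177). Tfap2c (1.84) and the keratin gene Krt8 (0.98) were among them, and the list had an adjusted p = 0.108 with an estimated correlation and 0.0535 without EpiSC replicate 1.

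The other 14 tested lists did not pass in Epi-Sox2 against EpiSC, with camera adjusted p-values from 0.0720, for the immediate early list, to 0.988, for the mesenchymal list. The immediate early list had 4 members higher and 0 lower of 13, among them Junb (0.91), and passed without the detection filter (0.0429). The primed pluripotency list had 1 member higher and 4 lower of 14, with Fgf5 and Car4 (-1.18) lower and the Nodal inhibitor Lefty2 2.31 higher. The FGF and ERK list had 5 higher and 2 lower of 15 (5 and 3 adjusted over the list alone), with Fgf4 (1.84) and the ERK phosphatase genes Dusp4 (1.65) and Dusp6 (1.01) higher while Fgf5 and Fgf8 were lower. Of 16 fibroblast markers 2 were higher and 0 lower, with Acta2 2.47 higher. In the shared pluripotency, Nodal, FGF and imprinted lists the median and the mean difference had opposite signs, as did the mesenchymal list's median (0.20) and its test. No member of the Hox and Cdx list or of the sex-chromosome list passed.

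In Epi-Sox2 against EpiSC 1917 of 9620 genes passed, 1013 higher and 904 lower, and 230 were higher and 73 lower by at least 1 log2 unit. The count was 1097 with only the arrays of the pair of groups, 672 without Epi-Sox2 replicate 1 and 921 without Epi-Sox2 replicate 2. The labels give conditioned medium for Epi-Sox2 and no medium for EpiSC, so medium and Sox2 cannot be told apart here.

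The third comparison asked how cells of the E3 line with the Oct4 reporter on differed from cells with it off. Pou5f1 itself was not higher in EpiSC-GFP+ (-0.38 ± 0.13, adjusted p = 0.0494), and its other detected probe differed by 0.03. Ooep rose by 5.24 ± 0.12 (adjusted p = 1.7e-08), Dnmt3l by 3.84 ± 0.13 (adjusted p = 1.12e-07), Esrrb by 3.64 ± 0.15 (adjusted p = 3.22e-07) and Nanog by 1.26 ± 0.19 (adjusted p = 0.00152). Wnt8a, a signalling protein of the early streak, fell by 2.55 ± 0.15 (adjusted p = 5.35e-06), and Fgf5 fell by 2.20 ± 0.17 (adjusted p = 3.18e-05). Sox2 was higher by 0.39 ± 0.13 (adjusted p = 0.0458). The calls of both Sox2 and Pou5f1 were lost with the authors' values (adjusted p = 0.0679 and 0.0705), with only the arrays of the pair of groups (0.0617 and 0.0616), with the replicate block (0.0574 and 0.0581) and without any single ESC, Epi-Sox2, EpiSC-GFP+ or EpiSC-GFP- array (0.0510 to 0.180), and that of Pou5f1 also without the detection filter (0.0517).

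The other largest rises in EpiSC-GFP+ were those of the cell-surface peptidase Dpp4 (at least 11.1-fold), Rbmxl2 (at least 13.2-fold), the secreted phospholipase gene Pla2g1b (4.25), Rhox5 (4.18, detected on 1 of 2 EpiSC-GFP- arrays), the X-linked gene Xlr4a (at least 9.16-fold) and Gstp2 (4.10). The other largest falls were those of Gdpd3 (-2.41), Them5 (at least 3.81-fold lower), Emp3 (-2.01), the lipid synthesis gene Mogat2 (-1.98), the peptide transporter gene Tap2 (at least 3.57-fold lower) and the adhesion gene Nrcam (-1.86). The other detected Mogat2 probe differed by 0.08 and did not pass.

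Of 18 naive pluripotency genes 16 rose in EpiSC-GFP+ and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 1.71e-19, and adjusted p = 0.0032 with an estimated correlation). Dppa5a (3.67), Zfp42 (3.27) and the reprogramming factor Klf4 (at least 7.40-fold for its brightest probe, and 1.73 log2 for the least changed of 3) were among them. Of 11 germ line genes 6 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.88e-04). Tex19.1 (3.41), Dppa3 (2.25) and Piwil2 (at least 2.18-fold) were among them, and the list had an adjusted p = 0.0646 with an estimated correlation. Of 8 DNA methylation genes 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00989). They were Dnmt3l and the corepressor gene Trim28 (0.48), whose call was lost with the authors' values (adjusted p = 0.0659) and without any single ESC, EpiSC-GFP+ or EpiSC-GFP- array (0.0562 to 0.125), and the list had an adjusted p = 0.145 with an estimated correlation. Of 13 immediate early genes 3 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0307). Fosb (1.53, detected on 1 of 2 EpiSC-GFP- arrays) and Fos (1.00) rose, and the list had an adjusted p = 0.169 with an estimated correlation, 0.0587 with the stricter detection filter and 0.0704 without EpiSC-GFP- replicate 2.

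The other 16 tested lists did not pass in EpiSC-GFP+ against EpiSC-GFP-, with camera adjusted p-values from 0.0939, for the imprinted list, to 0.990, for the trophectoderm list. The imprinted list had 1 member higher and 4 lower of 14 (1 and 5 adjusted over the list alone), with the cell cycle inhibitor Cdkn1c lower (-1.51), and passed with cyclic loess (0.0400), without the detection filter (0.0101) and without EpiSC-GFP- replicate 2 (0.0450). Of 11 primitive streak and mesoderm genes 2 were lower and 0 higher (camera adjusted p = 0.258), Fgf8 (-1.77) and Gsc (at least 2.26-fold lower), and the list passed with cyclic loess (0.0400) and median scaling (0.00886). The glycolysis and hypoxia list, with Pfkp 1.11 higher (0.39, not called, for its other probe), passed without the detection filter (0.0410). The shared pluripotency list had 4 higher and 2 lower of 11 (5 and 2 adjusted over the list alone), with Dppa4 (3.49, and 0.12 for the lowest of its 3 probes) and Sall1 (0.96, and 0.47, not called, for its other probe) higher. Of the primed pluripotency genes 1 was higher and 4 were lower of 14, among them Igfbp3 (-1.22), Lefty1 (-0.90) and the claudin gene Cldn6 (-0.79). In the BMP list 2 genes were higher and 0 lower of 11, with Bmp4 1.62 higher. In the shared pluripotency, primed, FGF and cell cycle lists the median and the mean difference had opposite signs, as did the trophectoderm list's median (0.07) and its test. The Hox and Cdx list had 1 member higher and 1 lower of 4. Meis1 was lower (-1.27), and the other was Cdx1, which was not detected in either fraction and whose call was lost under most alternatives, among them cyclic loess (adjusted p = 0.823) and the replicate block (0.0651), and no member of the sex-chromosome list passed.

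In EpiSC-GFP+ against EpiSC-GFP- 2566 of 9620 genes passed, 1293 higher and 1273 lower, and 359 were higher and 188 lower by at least 1 log2 unit. With median scaling the share of calls that were higher was 37.2% against 50.4%, and the median difference moved from -0.01 to -0.18. The count was 1705 without EpiSC-GFP- replicate 2, 1421 without EpiSC-GFP+ replicate 1 and 1441 without EpiSC-GFP+ replicate 2.

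Both fractions were also set against ESC, to ask whether either resembled embryonic stem cells. Otx2, detected on 1 of 2 ESC arrays, was 4.42 ± 0.14 higher in EpiSC-GFP+ than in ESC (adjusted p = 1.83e-08), Nanog fell by 3.01 ± 0.19 (adjusted p = 4.74e-07) and Pou5f1 was 1.53 ± 0.13 higher (adjusted p = 3.22e-06). Chst1 and Gbp2 were at least 18.5-fold and at least 14.8-fold higher, although the other Gbp2 probe differed by 0.45 and was not called. The largest falls were those of Klhl13 (at least 42.6-fold lower), Cacybp (at least 45.9-fold lower) and the membrane protein gene Vapa (-5.57). The Klhl13 and Cacybp probes were among those bright on the ESC arrays only. In EpiSC-GFP- Nanog fell by 4.27 ± 0.19 (adjusted p = 4.25e-08), Pou5f1 was 1.92 ± 0.13 higher (adjusted p = 5.38e-07) and Car14 was 5.37 ± 0.16 higher (adjusted p = 8.72e-09). Chst1 and Gbp2 were at least 47.2-fold and at least 36.5-fold higher, and the largest falls were those of Ooep (-6.51), the Polycomb gene Eed (-6.36, detected on 1 of 2 EpiSC-GFP- arrays) and Vapa (at least 45.2-fold lower). Eed and Vapa had only 1 probe past the filter, so their falls may also be specific to the probe.

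The Pou5f1 rises rested on 1 of its 2 detected probes, as the other differed by -0.05 in EpiSC-GFP+ and -0.07 in EpiSC-GFP- and was not called. Sox2 depended on the probe and the scaling in these comparisons. Its brightest probe was 0.35 ± 0.13 higher in EpiSC-GFP+ than in ESC (adjusted p = 0.0300), a call lost with cyclic loess (0.913), with median scaling (0.251) and without any single array of either group (0.0609 to 0.149), while its other probe was called lower and was not detected on either EpiSC-GFP+ array. In EpiSC-GFP- the brightest Sox2 probe differed by -0.04 ± 0.13 (adjusted p = 0.797), and by -0.46 with cyclic loess (0.00784). In all, 6597 genes passed in EpiSC-GFP+ against ESC (4000 higher and 2597 lower) and 6937 in EpiSC-GFP- against ESC (4092 higher and 2845 lower). The share higher in EpiSC-GFP+ against ESC was 60.6%, and 50.6% with cyclic loess, where the median difference moved from 0.24 to 0.06. In EpiSC-GFP- against ESC the share was 59.0%, and 49.2% with cyclic loess (3455 higher and 3570 lower), where the median difference moved from 0.22 to 0.02. Of 2426 genes with more than 1 detected probe, 469 and 462 had probes called in opposite directions in these 2 comparisons.

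The changes in Epi-Sox2 and in EpiSC-GFP+, which share no array, were set side by side. Of the genes called in both, 342 were higher in both comparisons, against 136 expected of independent lists (Fisher's exact test odds ratio 4.10, p = 1.21e-70), and 245 were lower in both, against 119.6 expected (odds ratio 2.78, p = 7.39e-32), while 175 went in opposite directions. Across genes, which are not independent replicates, the log2 differences had a Pearson r of 0.345 and a Spearman rho of 0.211. Dppa5a, Dppa4, Esrrb, Ooep, Dnmt3l, Rbmxl2 and Gstp2 were among the genes higher in both, and Fgf5, Fgf8 and Them5 were lower in both. The count of genes higher in both was 172 without Epi-Sox2 replicate 1, and the count of genes lower in both was 85. With the authors' values 139 genes were lower in both, and without background correction 374 were.

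EpiSC-GFP+ also differed from EpiSC-GFP- in part in the direction in which ESC differed from EpiSC. Of the genes called in both comparisons, 582 were higher in EpiSC-GFP+ and in ESC (339 expected, odds ratio 2.70, p = 3.03e-56 by Fisher's exact test) and 909 were lower in both (515 expected, odds ratio 4.50, p = 1.19e-127), with 358 in opposite directions. Ooep, Rhox5, Rbmxl2, Dppa5a and Dnmt3l were higher in both, and Fgf5 and Fgf8 lower in both. The Pearson r across genes was 0.393 and the Spearman rho 0.342. The count of genes lower in both was 581 with cyclic loess and 471 without EpiSC-GFP+ replicate 1.

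**Figure D2:**
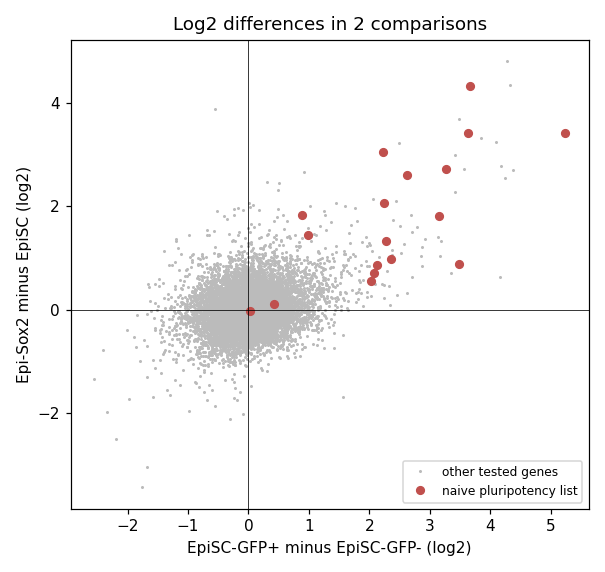
Log2 difference of each tested gene between EpiSC-GFP+ and EpiSC-GFP- (horizontal axis) and between Epi-Sox2 and EpiSC (vertical axis). Each point is a gene, and the 18 tested naive pluripotency genes, in red, lie mostly to the upper right, with 15 called higher in Epi-Sox2 and 16 in EpiSC-GFP+.

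Each array was placed on a line from the ESC mean, at 0, to the EpiSC mean, at 1, over the 3109 genes that passed between those groups with a difference of at least 1 log2 unit. Epi-Sox2 lay at 0.904 ± 0.011 (SD, n = 2), EpiSC-GFP+ at 0.922 ± 0.002 and EpiSC-GFP- at 1.10 ± 0.006, beyond EpiSC. The gap of EpiSC-GFP+ to EpiSC-GFP- was larger than the spread of their replicates. The smallest p an exact two-sided permutation test of 2 against 2 arrays can give is 0.333, however. The EpiSC arrays set both the genes and the end of the line, so their spread cannot judge the gap of Epi-Sox2 to EpiSC. The log2 differences of Epi-Sox2 against EpiSC and of ESC against EpiSC-GFP-, which share no array, had a Pearson r of 0.107 across genes. Single genes departed from this average in different ways: Dppa5a stood at 12.80 in Epi-Sox2, 14.39 in EpiSC-GFP+ and 10.72 in EpiSC-GFP-, against 14.85 in ESC and 8.48 in EpiSC, while Klf4 stood at 5.53 in Epi-Sox2, against 8.43 in ESC. The line rests on a comparison in which probes of 308 genes went in opposite directions.

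**Figure D3:**
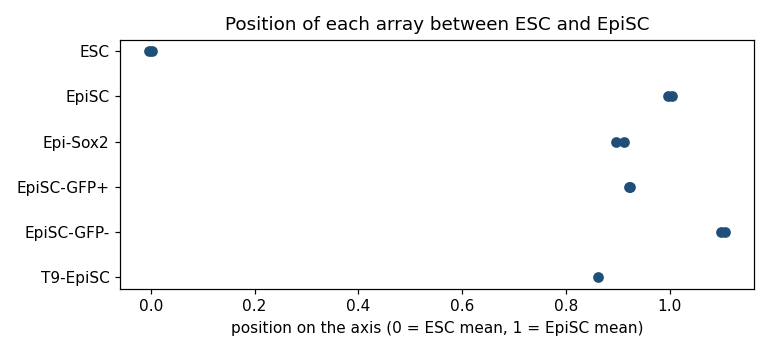
Position of each array (dots) on the line from the ESC mean (0) to the EpiSC mean (1), in units of that distance, by kind of culture. The Epi-Sox2 and EpiSC-GFP+ arrays lie a little on the ESC side of EpiSC, at means of 0.904 and 0.922, and the EpiSC-GFP- arrays lie beyond EpiSC, at 1.10.

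T9-EpiSC had 1 array, so that its differences have no replicate check and no test. Against EpiSC 571 genes were higher and 552 lower by at least 1 log2 unit, and against ESC 1600 were higher and 1413 lower. These counts against EpiSC were 230 and 169 without background correction and 1107 and 1193 with the authors' values, and against ESC 770 and 768 without background correction and 2413 higher with the authors' values. More genes were lower than higher against ESC with cyclic loess (1899 and 1470), and the numbers were 1699 and 1702 with median scaling. Nanog was 1.31 and Sox2 1.09 above EpiSC, and Pou5f1 differed by -0.78. On the line from ESC to EpiSC the array lay at 0.861.

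The gene lists of T9-EpiSC were set against 10000 random lists of the same size and mean expression, as a description of these arrays. Against EpiSC the mesenchymal list had a median difference of 0.85 (percentile 100), with the zinc finger gene Zeb1 2.58 and the matrix gene Tgfbi 1.68 higher. The epithelial list had a median of -0.74 (percentile 0.02), with Cldn4 at -1.91 and Cdh1 at -1.75. The neuroectoderm list had a median of 1.42 (percentile 100), with the homeobox genes Irx3 (3.27) and Meis1 (2.54) higher, the glycolysis and hypoxia list 0.93 (percentile 100), with Egln3 2.12 higher, and the BMP list 0.81 (percentile 99.97), with Id1 2.39 higher. The streak list had a median of 0.62 (percentile 99.89), the endoderm list 0.44 (99.25), the Wnt list 0.46 (99.1) and the trophectoderm list 0.37 (97.83). The fibroblast list had a median of 0.55 (percentile 99.94), with Acta2 2.99 and the proteoglycan gene Dcn at least 2.87-fold higher, on the same array as these shifts. Naive pluripotency genes had a median of 0.03 (percentile 73.59), with members far apart: Gbx2 was 4.44, Klf2 2.02 and Nr5a2 at least 15.4-fold higher, and Fgf4 at least 2.08-fold lower. Primed genes had a median of -0.06 (percentile 55.28). The FGF and ERK list had a median of 0.12 (percentile 85.83), with Etv4 (-2.22), Spry4 (-1.66) and Fgf4 lower and Fgf15 (1.32) higher. The T9 line, its culture on fibroblasts and the withdrawal of Fgf2 cannot be told apart with this array.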

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

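The tests of labelling or hybridization, of feeder RNA and of a share of EpiSC-GFP+ cells, the share of disagreeing genes before the restriction to detected probes, and the alternatives based on probes that agree and on leaving out the T9-EpiSC array, were chosen after the results they concern were seen, and how those 3 tests are read was corrected once more after their values were known.

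Xist, the transcript that coats an inactive X chromosome, stood out on the T9-EpiSC array, which entered no tested comparison. Its 2 probes read 8.46 and 6.60 (log2) there, while they were detected on 0 of the other 10 arrays, which reached at most 4.84 and 5.01. The Y-linked gene Eif2s3y read 4.28 and was not detected, although all samples are labelled male and the other 10 arrays read 5.37 to 8.96. The lowest of these were the sorted E3 arrays, at 5.37 to 5.88, where the lowest detected signals were 5.05 to 5.38. Other Y-linked genes were of little use, as Kdm5d, Usp9y and Uty were detected on 1, 2 and 4 of the 11 arrays. RNA of feeder cells alone stays open, because the Eif2s3y test could not decide it. Eif2s3y, taken at the floor of its array (4.77), lay 0.60 under the lowest other array (-0.60), less than the SD of 1.35 between the means of the other 5 groups. An undetected value counts as that floor, so the gap could not have passed this SD. The T9-EpiSC cells were harvested without the fibroblasts they grew on. The fibroblast list stood high against EpiSC (median 0.55, percentile 99.94) but not against ESC (0.14, percentile 64.16). The ESC arrays, without Xist, read Fbln2 at 8.12 and Acta2 at 10.55. The T9-EpiSC array read these at 7.13 and 10.84, while Col3a1 (4.39) and Lox (4.50) were not detected on it. Cells with 2 X chromosomes and no Y remain a candidate explanation, as a hypothesis against the label: 3 of 3 measured genes that escape X inactivation lay above the 8 other epiblast stem cell arrays, Eif2s3x at 10.36 (highest other 9.99), Kdm6a at 9.70 (9.37) and Ddx3x at 7.43 (6.65), while Kdm5c was not among the tested genes and a line-specific level of Eif2s3y stays open.

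Probes of one gene disagreed in EpiSC against ESC, where 320 of 2426 genes had probes whose log2 differences lay more than 2 apart, against 4 in Epi-Sox2 against EpiSC. Signal near background was argued against, since the share of such genes fell little when all probes had to be detected on all 4 arrays. It was 11.2% there (141 of 1262), against 13.2% of all genes with more than 1 probe past the filter. The number was 0 of 1466 in Epi-Sox2 against EpiSC, where the differences were smaller and reached such a range less easily. Background correction or normalization was argued against as the whole cause, since genes with probes called in opposite directions numbered 308 and at least 267 under 5 other ways of correcting and scaling. Labelling or hybridization of the ESC arrays that differed from the rest cannot be told apart from transcript forms that differ between the cell types. Both would put such ranges on pairs with ESC (320 to 538 genes) more than on the 6 other pairs (at most 41). These counts also grow with the size of the differences, whose SD over all probes was 1.18 in EpiSC against ESC. It was 0.45 in Epi-Sox2 against EpiSC and 0.53 in EpiSC-GFP+ against EpiSC-GFP-. The correlation between 2 probes of a gene was 0.57, 0.64 and 0.54 in that order. It was 0.41 in EpiSC-GFP+ and 0.48 in EpiSC-GFP- against ESC, so by this measure pairs with and without ESC overlapped. No probe positions were used here, so values against ESC may hold a probe-specific part in either case. The ESC arrays also stood apart before normalization, with mean signals of 623 and 595 against 199.7 to 371 on the other 9 arrays. No slide is named, so a technical cause of this gap was not tested.

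Epi-Sox2 and EpiSC-GFP+ shared more higher genes than expected of independent lists, 342 against 136. Scaling between arrays was argued against, since the ratio of shared to expected genes was 2.16 or more under 5 other ways of correcting and scaling. A larger share of EpiSC-GFP+ cells in the Epi-Sox2 cultures stays open. If Epi-Sox2 were a mixture of EpiSC and EpiSC-GFP+ cells, 16 naive pluripotency genes would imply shares with a 25th percentile of 20.5%, a median of 29.6% and a 75th percentile of 42.3%, a ratio of 2.06 within the bound of 3 set after the pattern was seen, but they ran from 7.77% for Klf4 to 88.1% for Fgf4 and 105% for Gbx2, a spread that a single share does not explain by itself, and the profile comes from another line. An effect of Sox2, which the design names, may also account for the shared genes and was not tested apart from that share or from the medium.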

How the results depend on the processing

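The alternatives that keep only genes whose probes all passed in one direction, or leave out the T9-EpiSC array, were chosen after the data were seen; the others were planned. Over 413 results, in 7621 pairs of a result and an alternative, named genes kept their side of the threshold, with called genes in their direction, in 2788 non-leave-out cases, lost the call in 90 and gained one in 43; with an array left out these numbers were 2727, 171 and 32. In 81 cases counted as unchanged, over genes and lists, a value without a call changed sign. Otx1 (-0.00934) and Cdx1 (-0.20) turned direction with median scaling in EpiSC-GFP+ against EpiSC-GFP-. Unless stated, the cause was not tested. In the order EpiSC against ESC, Epi-Sox2 against EpiSC, EpiSC-GFP+ against EpiSC-GFP-, EpiSC-GFP+ against ESC and EpiSC-GFP- against ESC, the calls numbered 6394, 1785, 2473, 6591 and 6922 with the replicate block. That block ended the Sox2 and Pou5f1 calls between the sorted fractions, among others. At 1 log2 unit or more the calls numbered 3109, 303, 547, 3500 and 3990. Among genes whose probes agree they numbered 785, 147, 167, 782 and 870, of the 2426 genes with more than 1 detected probe. Without T9-EpiSC they were 6396, 1967, 2593, 6568 and 6917. With only its own arrays Epi-Sox2 against EpiSC had 1097 calls, from fewer arrays; leaving out 1 array gave 672 to 1949, and 1421 to 3062 in EpiSC-GFP+ against EpiSC-GFP-. With an array left out, a lone array was assumed to vary like the other groups. With an estimated correlation 2, 1 and 1 lists passed. Genes lower in both Epi-Sox2 and EpiSC-GFP+ numbered 374 without background correction and 139 with the authors' values, and leaving out arrays gave 172 to 393 higher and 85 to 292 lower; genes lower in EpiSC-GFP+ and ESC numbered 581 with cyclic loess and 471 to 1111. On the line from ESC to EpiSC, Epi-Sox2 lay at 0.883 with the first arrays and 0.860 with agreeing probes (472 genes). EpiSC-GFP+ lay at 0.918 with the offset of 50, 0.913 without background correction, 0.912 with median scaling, 0.911 with the authors' values and with the first arrays, 0.926 with all genes and 0.868 with agreeing probes. EpiSC-GFP- lay at 1.09 without background correction, 1.05 with cyclic loess, 1.02 with median scaling and 1.07 with the first arrays, and T9-EpiSC at 0.874 with cyclic loess, 0.871 with median scaling, 0.850 with the authors' values, 0.847 with the first arrays and 0.844 with all genes. T9-EpiSC against EpiSC had 291 genes higher and 228 lower by 1 log2 unit with the offset of 50, 230 and 169 without background correction, and 1107 and 1193 with the authors' values; against ESC 938 and 914, 770 and 768, and 2413 higher. A median signal as low as 1.24 times the lowest signal of an array limits what dim probes can show. Groups of 2 leave too few other splits of the arrays for a small p.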

Other observations

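The test of the difference between the Sox2 and the reporter effects, the third overlap and the choice of the T9-EpiSC genes named here were made after the results were seen.

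The effect in Epi-Sox2 against EpiSC and that in EpiSC-GFP+ against EpiSC-GFP- were compared gene by gene in one limma model, and 1538 of 9620 genes differed, 806 with a more positive and 732 with a more negative log2 difference in Epi-Sox2, genes not detected in a group included. Vstm2l rose in Epi-Sox2 but not in EpiSC-GFP+ (difference of effects 4.44, adjusted p = 1.98e-05), and Acta2 (2.17) and Lefty2 (1.82) were also higher by more in Epi-Sox2. The effect on Ooep (-1.83) and on Nanog (-1.36, adjusted p = 0.0108) was larger in EpiSC-GFP+. For Dppa4 (0.21, adjusted p = 0.389) and Esrrb (-0.21, adjusted p = 0.529) no difference of the effects was detected, which does not show that they were alike.

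Genes called in Epi-Sox2 against EpiSC were also set against those of ESC against EpiSC-GFP-, which share no array with them. Of these, 345 were higher in both, against 299.6 expected (Fisher's exact test odds ratio 1.26, p = 0.00105), 547 were lower in both, against 385 expected (odds ratio 2.23, p = 4.79e-30), and 628 went in opposite directions, with a Pearson r of 0.107 across genes.

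The T9-EpiSC array stood apart from EpiSC by genes of several kinds. The immediate early gene Fos was 5.16 higher, Igfbp5, a binding protein of insulin-like growth factors, 4.80, the growth factor gene Ptn 4.65 and Nckap1l 4.45, the last detected on 1 of 2 EpiSC arrays, while Dok2 (-3.92), Cops8 (-3.90), the mitochondrial import gene Tomm22 (-3.45) and Psors1c2 (-2.85) were lower. Against ESC, Otx2 (5.38, detected on 1 of 2 ESC arrays), Cd59a (5.35), Psg23 (5.18) and Car14 (4.97) were highest, and Ooep (-6.80), Esrrb (-6.21), Mylpf (-5.88) and Dppa4 (-5.84) lowest, among genes measured on both sides. These are differences of 1 array and have no test.

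Across the probes of genes with more than 1 detected probe, 67.6% of the within-gene variance lay on a single component, on which the ESC arrays scored highest. In units of the mean ESC score, T9-EpiSC lay at 0.16 and the EpiSC and Epi-Sox2 arrays at -0.05 to -0.11. The sorted E3 fractions lay further off, at -0.43 to -0.48, so this component did not set the ESC arrays apart alone. Of the 25697 probes, 93 read above 8 on both ESC arrays and under 6 on the other 9, and 11 did the reverse, at levels chosen after the data were seen. The 93 included probes of Klhl13, Cacybp, Hprt, Hspa5 and Ywhae. The 11 included probes of Otx2, Gbp2, Chst1, Car14, Glrx and Cd59a.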
